A study of Mus musculus with 8 samples.

How the data were processed

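Total RNA of endothelial cells sorted from the colon of healthy C57BL/6J mice aged 8 weeks was measured on 8 single-colour expression arrays. Per the labels, opened colons were digested with collagenase and DNase, and the suspension was sorted by flow cytometry with antibodies to CD31, podoplanin and CD45.2 straight into lysis buffer. The gates themselves are not given in the sources used here. RNA was amplified by a linear isothermal method primed at the poly(A) sequence and at random along transcripts, and the single-stranded cDNA was fragmented and labelled with biotin. Per the series design, the 4 pairs were chosen on the quality of the extracted and amplified material.

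The deposited table holds log2 values, 1 column per array. MAS5, which summarises the perfect-match and mismatch probes of a probe set into 1 signal, is named in the submitters' processing notes, and its version is not given in the sources used here. That these are log2 values of scaled signals was read from the values: the 2% trimmed mean of the linear signals was 100.04 on each of the 8 arrays, while array medians differed and no centring per gene or quantile normalization was seen. Scaling to a trimmed mean assumes the same total signal in both cell types. Detection calls were not used here. The values entered all tests as deposited, with no pseudocount and no further normalization between arrays.

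The table has 45101 probe sets, 64 of them controls that were left out of the tests. Names came from the platform annotation of 2016 and were updated through the gene number to the symbols of the RefSeq annotation of GRCm38.p6. Of the probe sets, 34945 had 1 gene (34741 of these matched through the gene number, 204 kept the annotated symbol), 932 had several and 9160 had none, and probe sets with several or none named no gene. The 34945 probe sets stand for 18193 genes. The arrays' files name no genome build, so no coordinates are given.

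Samples were grouped by their titles into 4 arrays of lymphatic endothelial cells (LEC) and 4 of blood vascular endothelial cells (BEC). The series design states that LEC and BEC came in animal-matched pairs, so the replicate number is the mouse. The correlation of same-mouse deviations from the group means over the 13259 genes tested was 0.142, 0.0776, 0.181 and 0.0510 for mice 1 to 4, and for 3 of the 4 mice it was above the correlation with any other mouse. The mice are separate animals, so the p-values of genes measure the spread between animals together with that of the amplification and the array. The main fit leaves the pairing out.

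The main test was fixed before the data were examined. For each gene the probe set with the highest mean over the 8 arrays was taken and kept where its value was above the 40th percentile of its array on at least 4 of the 8 arrays. The 13259 kept genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with the cell type as the only term. P-values are two-sided and adjusted by the method of Benjamini and Hochberg over all 13259 genes, and a gene is called at an adjusted p under 0.05. Differences are LEC minus BEC on the log2 scale (logFC) and stand with their moderated standard error. The fit had 6 residual and 7.35 prior degrees of freedom.

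A background level was set for each array after seeing the data, as the 95th percentile of 27 control probe sets for Bacillus subtilis transcripts, and lay between 3.43 and 4.88 on the log2 scale. Where the dimmer group had at least 1 array under that level, the ratio is given as "at least", with values raised to the background level on each array before the group means were taken. This bound is a statement about means of the 1 probe set taken for the gene, and the adjusted p beside it is that of the fit on the deposited values. Other probe sets of the gene can give a smaller or larger difference. No value below background is read as absence of the transcript.

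Gene lists were fixed before the data were examined: 30 lists with 709 entries, of which 678 had a named probe set. Of these, 28 were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 28 lists, and camera with an estimated correlation and fry were run beside it. Further lists of epithelial, fibroblast and enteroendocrine genes (36, 33 and 30 genes) were written for the closing section after the first results and before the values of their genes were seen. The sort antigens and the sex-linked genes were not tested as lists and were read per array. The camera tests compare a list with all other genes, whereas fry tests whether the genes of a list move, on balance, one way. For each list, members called over all genes stand beside the number called when adjusted over the list alone.

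The genes named in the text follow a rule fixed beforehand. It takes 9 genes chosen in advance (Pecam1, Pdpn, Ptprc, Prox1, Lyve1, Flt4, Sema3a, Nrp1 and Nrp2). It adds the 10 largest differences in each direction among called genes with the same sign in all 4 mice and a mean above the median of kept genes in the brighter group. From each biological list it takes up to 3 called members in the prevailing direction and 1 in the other. From each list of other cell types it takes up to 2 called members, or the member with the lowest p where none was called. Other genes are named as chosen after their values were seen. Measures with 1 value per array were compared by an exact two-sided permutation test over the 70 arrangements of 4 against 4, whose smallest possible p is 0.029. An exact sign-flip test over the 16 sign patterns of the 4 pairs was added after the data were seen.

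The fit and the set test were tested on simulated data. In 20 simulated data sets of the 13259 genes with their measured means and spreads, 200 genes each were changed by a known amount between 4 and 4 arrays. The share called was 0.375% for a log2 change of 1, 11.2% for 2, 27.6% for 3, 48.1% for 4 and 75.2% for 6, and 5.10% of all calls were false. A list of 25 genes shifted by 2 was called in all 20 data sets and none of 560 unshifted lists was. Simulated genes varied independently of each other, so false calls of lists whose genes vary together were not tested. The median standard error was 0.83 over all genes, and the p-values of genes rest on 4 mice.

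The alternatives were the mouse as a fixed or random block, no intensity trend, array quality weights, quantile or median scaling, a floor at the 40th percentile, no filter or a stricter one at the 60th percentile, other ways to combine probe sets, and leaving out each array and each mouse. Adding 16 to the linear signal and scaling to 18 hybridisation control probe sets were chosen after seeing the data. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.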

Results

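Lymphatic and blood vascular endothelial cells were compared in the normal mouse colon. Lymphatic endothelial cells (LEC) line the vessels that drain fluid, lipid and leukocytes from tissue, and blood vascular endothelial cells (BEC) line arteries, capillaries and veins. Both were sorted from the same 4 mice, 3 female and 1 male, which gave 4 arrays of LEC and 4 of BEC. Between 9593 and 11701 of the 13259 genes tested lay above the background level of an array. Spearman correlations between arrays ran from 0.556 to 0.770, and LEC replicate 1 had the lowest median correlation with its own group (0.601, against 0.711 to 0.724 for the other LEC arrays). The first principal component placed all 4 BEC arrays on the side opposite to the 4 LEC arrays.

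The antigens and sex-linked genes were read first as a check of the labels. Podoplanin (Pdpn), whose protein was stained for the sort, had a log2 signal of 12.24 ± 0.07 in LEC and 3.39 ± 0.59 in BEC (mean ± SD, n = 4 each), at least 323-fold higher in LEC with 2 of 4 BEC arrays above background (limma, adjusted p = 2.34e-06). CD31 (Pecam1), an endothelial antigen also stained for the sort, stood at 12.10 ± 0.44 in BEC and 11.49 ± 0.60 in LEC (logFC -0.61 ± 0.33, adjusted p = 0.439, lower in LEC in 4 of 4 mice). CD45 (Ptprc) did not pass the filter and ranged from -1.27 to 7.58 over the 8 arrays. Pdpn is a sort antigen, so its difference is no independent finding. Xist, expressed from the inactive X chromosome, was between 10.48 and 11.60 on the 6 female arrays and 1.67 and 1.97 on the male pair. Y-linked Eif2s3y was between 0.10 and 3.13 on the female arrays and 7.03 and 7.77 on the male pair, so LEC and BEC of replicate 4 both matched the labelled sex. The ranges of the dimmer Y-linked genes Kdm5d and Uty overlapped between the sexes, at 0.75 to 5.28 and 0.09 to 4.55 on the female arrays and 4.26 to 6.26 and 4.18 to 5.70 on the male pair.

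**Figure D1:**
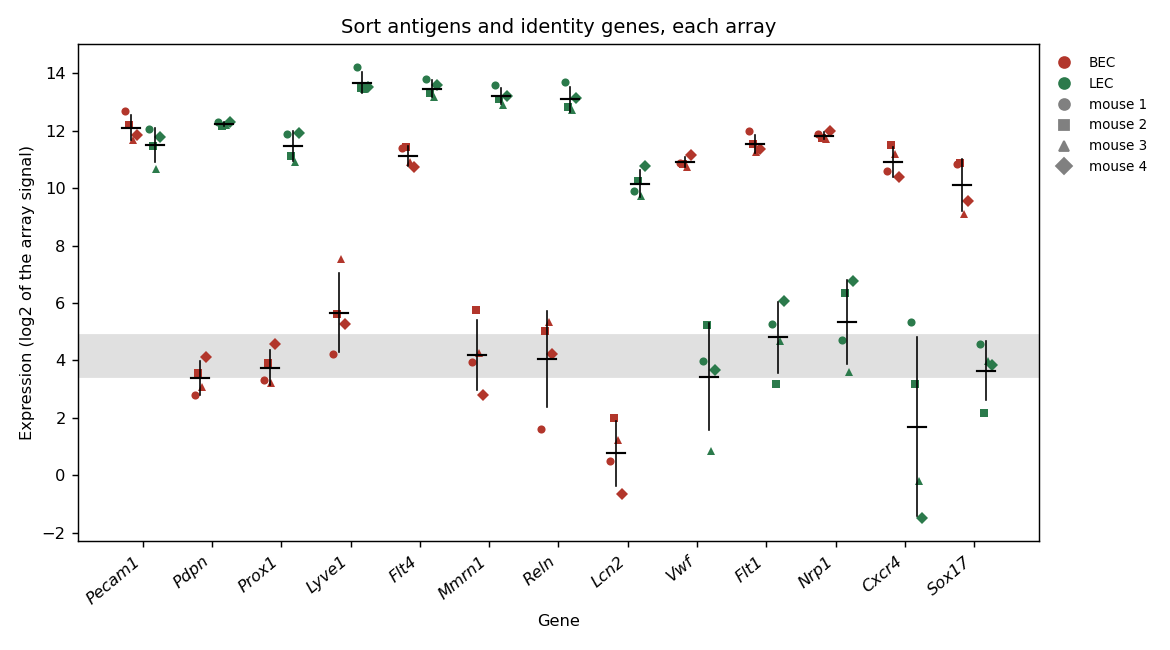
Log2 array signal (vertical axis) of the sort antigens Pecam1 and Pdpn and of lymphatic and blood vascular genes (horizontal axis) on each of 4 BEC and 4 LEC arrays; symbols mark the mouse, bars the mean and lines 1 SD, and the grey band spans the arrays' background levels (3.43 to 4.88). Pecam1 is bright in both cell types, whereas Pdpn, Prox1, Lyve1, Mmrn1, Reln and Lcn2 are bright in LEC, and Vwf, Flt1, Nrp1, Cxcr4 and Sox17 in BEC.

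LEC and BEC differed at 540 genes, 234 higher and 306 lower in LEC, and 539 of the 540 had the same sign in all 4 mice. That agreement in sign was largely set by the call itself, which needs a difference large against the spread within groups. Among brighter genes ordered by fitted logFC, those at the top towards LEC were Adgrg3, an adhesion G protein-coupled receptor (at least 106-fold), Lcn2, the iron-siderophore carrier lipocalin 2 (at least 87.6-fold), Reln, the extracellular glycoprotein reelin (at least 319-fold), Mmrn1, multimerin 1 (at least 422-fold), and Tgfb3, a transforming growth factor (at least 54.3-fold). Thy1, a cell surface glycoprotein (at least 303-fold), Abi3bp (at least 42.9-fold), Lyve1, a hyaluronan receptor (at least 246-fold), and the matrix protein tenascin XB (Tnxb, at least 104-fold) followed with Pdpn. Without BEC replicate 3 the bound for Lyve1 was 372-fold. Adjusted p-values of these genes lay between 2.34e-06 for Pdpn and 2.43e-04 for Abi3bp. Towards BEC the fitted logFC was furthest from 0 for Entpd1, the ectonucleotidase CD39 (at least 176.6-fold), Sema3g, a secreted semaphorin (at least 110.6-fold), Cxcr4, the receptor of CXCL12 (at least 93.0-fold), Chgb, the secretory granule protein chromogranin B (at least 82.8-fold), and Aqp7, an aquaglyceroporin (at least 113-fold). They were followed by Cysltr1, a leukotriene receptor (at least 21.5-fold), Plscr2 (at least 44.2-fold), the phosphatase gene Ptprr (at least 47.0-fold), Exoc3l2 (at least 99.0-fold) and von Willebrand factor (Vwf, at least 85.7-fold). The BEC values of Chgb (adjusted p = 0.00222) spread from 5.43 in replicate 1 to 13.67 in replicate 4, and its bound was 275-fold without BEC replicate 1, 49.3-fold without replicate 3 and 41.0-fold without replicate 4.

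Much of the order by fitted logFC rests on values below background, and by the bounds alone it differs: Prox1 (at least 164-fold) stood above Tgfb3 and Abi3bp, and Flt1 (at least 87.3-fold) above Cysltr1 and Plscr2. The median absolute logFC of called genes was 3.96, and 230 and 306 of them differed by 2-fold or more towards LEC and BEC. The dimmer group was below background on all 4 arrays at 33 of the genes higher and 43 of the genes lower in LEC. At 312 called genes another probe set passed the filter. Limma called it in the opposite direction at 0 of these genes, and at 1 by an unadjusted p under 0.05. The size could differ between probe sets, so the bounds hold for the chosen one. Other kept probe sets gave a logFC of -7.45 to -4.28 for Entpd1 (bound -7.46), -4.05 for Aqp7 (bound -6.82) and 6.42 for Reln (bound 8.32). Larger differences than the bound were seen too, with 8.91 for Lyve1 (bound 7.94) and -11.51 for Aplnr (bound -6.38). The number of genes lower in LEC was 180 without BEC replicate 2 and 200 without BEC replicate 4. The split of 234 higher and 306 lower depended on scaling: with equal array medians it was 162 and 336, and with equal hybridisation controls, chosen after seeing the data, 123 and 280. These scalings moved the median logFC of all genes from 0.08 to -0.20 and -0.31, so directions of small differences are relative to the deposited scale.

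Genes known to mark lymphatic endothelium were higher in LEC as a list. Of 23 tested members of the lymphatic identity list, 19 were higher and 0 lower, and 20 were higher and 1 lower when adjusted over the list alone (camera, adjusted p = 6.61e-37, and adjusted p = 0.00296 with an estimated correlation). The sort antigen Pdpn is among the 19 and in the camera test, and is no independent finding. Prox1, the transcription factor that sets lymphatic fate, was 11.46 ± 0.52 in LEC and 3.75 ± 0.62 in BEC (SD, n = 4), at least 164-fold higher with adjusted p = 7.02e-06. Flt4, the receptor of VEGF-C, was bright in both cell types, at 13.47 ± 0.29 in LEC and 11.11 ± 0.35 in BEC, a 5.11-fold difference (adjusted p = 9.47e-05). The lymphatic valve list also stood higher (5 of 16 members higher, 1 lower, and 7 and 2 when adjusted over the list alone; camera, adjusted p = 0.0106), but its adjusted p was 0.229 with an estimated correlation. Its called members included Sema3a and Prox1, together with Cldn11, a claudin (at least 12.2-fold, adjusted p = 0.0196), whereas Nrp1 was lower. Cldn11 missed the threshold (adjusted p = 0.0523 to 0.0577) when BEC replicate 2, LEC replicate 2 or LEC replicate 4 was left out.

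Blood vascular genes were lower in LEC as a list. Of 26 tested members of the blood vascular identity list, 0 were higher and 18 lower, and 20 were lower when adjusted over the list alone (camera, adjusted p = 1.85e-28, and adjusted p = 0.00296 with an estimated correlation). Besides Cxcr4 and Vwf, the apelin receptor gene Aplnr was at least 83.3-fold lower in LEC (adjusted p = 1.64e-04). Of 22 arterial genes, 10 were lower and 0 higher, and 13 and 1 when adjusted over the list alone (camera, adjusted p = 6.54e-11, and adjusted p = 0.00897 with an estimated correlation). They were led by Sema3g, Cxcr4 and the VEGF and semaphorin co-receptor Nrp1. The venous list was divided, with Vwf, Aplnr and P-selectin (Selp, at least 8.84-fold, adjusted p = 0.00677) lower and Nr2f2, the venous and lymphatic transcription factor COUP-TFII, 7.80-fold higher in LEC (adjusted p = 0.00205). In total 2 of its 12 members were higher and 4 lower, with 2 and 5 when adjusted over the list alone, and camera placed the list lower in LEC (adjusted p = 0.0288). That call did not hold with an estimated correlation (adjusted p = 0.234), with the mouse as a replicate block (adjusted p = 0.0595), with the stricter filter (adjusted p = 0.0919), without BEC replicate 4 (adjusted p = 0.101) or without LEC replicate 3 (adjusted p = 0.0583). For Nr2f2 the adjusted p was 0.0524 with equal hybridisation controls and between 4.22e-04 and 0.0328 under the other alternatives.

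Genes expressed across endothelium were lower in LEC as a list. The list mean was 10.04 ± 0.07 in BEC and 9.11 ± 0.41 in LEC (SD, n = 4), lower in LEC in all 4 mice, with 0 of 22 members higher and 5 lower, and 4 and 7 when adjusted over the list alone. Camera gave an adjusted p of 1.69e-05, and the adjusted p was 0.176 with an estimated correlation. Called members included Clec14a, an endothelial C-type lectin (at least 22.3-fold, adjusted p = 0.00159), and Mcam, the adhesion molecule CD146 (at least 9.25-fold, adjusted p = 0.0302). Mcam missed the threshold (adjusted p = 0.0521 to 0.114) when BEC replicate 1, 2 or 3 or LEC replicate 2 or 3 was left out.

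Semaphorin genes went in both directions. Semaphorins are guidance ligands that act through neuropilins and plexins. Sema3a was 9.36 ± 1.05 in LEC and 3.20 ± 0.76 in BEC (SD, n = 4), at least 48.9-fold higher in LEC (adjusted p = 2.13e-04), and Sema3d was at least 98.8-fold higher (adjusted p = 3.59e-05). Sema4d was at least 10.1-fold higher (adjusted p = 0.0233, and at least 15.5-fold without BEC replicate 3), but its adjusted p was 0.0595 to 0.0782 without BEC replicate 1, 2 or 4 or LEC replicate 2, 3 or 4, and neither of its other kept probe sets was called (logFC 0.72 to 3.63). Sema3g was lower in LEC. The receptor gene Nrp1 was 11.82 ± 0.13 in BEC and 5.35 ± 1.47 in LEC, at least 82.7-fold lower in LEC (adjusted p = 8.56e-05). Nrp2 was bright in both, at 12.31 ± 0.79 in LEC and 10.64 ± 0.68 in BEC, 3.19-fold higher in LEC (logFC 1.67 ± 0.42, adjusted p = 0.0394, higher in 4 of 4 mice). None of the 3 other probe sets of Nrp2 was called (logFC 1.56 to 2.84), and leaving out any array but BEC replicate 4 and LEC replicate 3 raised its adjusted p to 0.0750 to 0.114. It was 0.125 with equal array medians and ran from 0.0158 to 0.271 over all alternatives. Over the 28 semaphorin, neuropilin and plexin genes tested, 4 were higher and 4 lower, with 6 and 4 when adjusted over the list alone. Over all 13259 genes, 234 were higher and 306 lower. Camera gave no shift of the list in 1 direction (adjusted p = 0.693, and adjusted p = 0.681 with an estimated correlation). A list that goes both ways can fail that test, so it does not speak against differences at these genes.

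**Figure D2:**
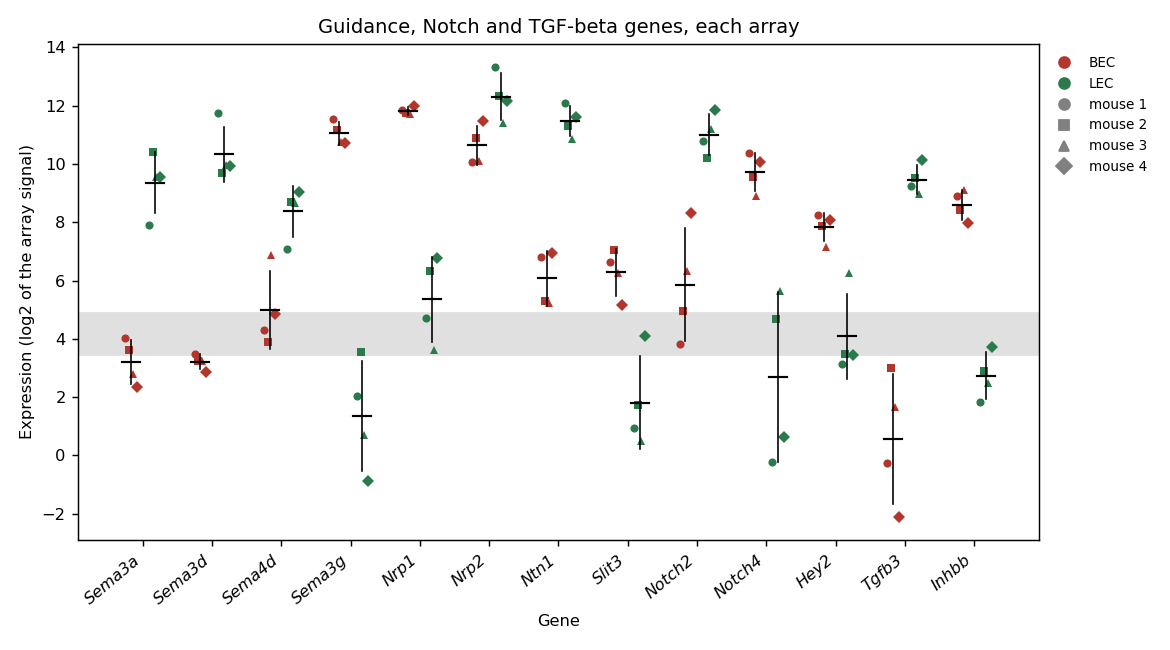
Log2 array signal (vertical axis) of semaphorin, neuropilin, netrin, slit, Notch and TGF-beta family genes (horizontal axis) on each of 4 BEC and 4 LEC arrays; symbols mark the mouse, bars the mean and lines 1 SD, and the grey band spans the arrays' background levels. Sema3a, Sema3d, Ntn1 and Tgfb3 are brighter on all 4 LEC arrays than on any BEC array, Sema3g, Nrp1, Slit3 and Inhbb the reverse.

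Of 29 other guidance genes, 1 was higher and 3 lower in LEC, as when adjusted over the list alone except for 1 more lower gene (1 and 4), and the list was not placed apart (camera, adjusted p = 0.982, with a mean and median logFC of 0.10 and a test direction below 0). The mean turned to -0.05 with quantile normalization. Equal array medians and equal hybridisation controls shift the logFC of every gene alike, so the means of -0.17 and -0.29 under them say nothing about the list itself. Netrin 1 (Ntn1) was 42.1-fold higher in LEC (logFC 5.40 ± 0.54, adjusted p = 8.56e-05). The ligand gene Slit3 was at least 3.99-fold lower (adjusted p = 0.0171), the receptor gene Epha4 at least 5.79-fold lower (adjusted p = 0.0368) and the ephrin gene Efnb1 4.10-fold lower (adjusted p = 0.0437). With the mouse as a replicate block the adjusted p was 0.0614 for Epha4 and 0.0814 for Efnb1, and both lost their call when any array but LEC replicate 1 was left out (0.0670 to 0.0978 for Epha4, 0.0643 to 0.141 for Efnb1). That of Slit3 was 0.0520 to 0.0784 without BEC replicate 1, 2 or 3.

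Notch pathway genes were lower in LEC as a list, with 1 of 21 members higher and 5 lower, and 2 and 7 when adjusted over the list alone (camera, adjusted p = 0.0141). The adjusted p was 0.176 with an estimated correlation. Among the receptors, Notch4 was at least 30.3-fold lower (adjusted p = 0.00269) and Notch2 at least 31.5-fold higher in LEC (adjusted p = 0.00202, and at least 53.4-fold without BEC replicate 4). The target gene Hey2 was at least 7.85-fold lower (adjusted p = 0.0148, and 0.0519 to 0.0547 without BEC replicate 1, 2 or 4), and the glycosyltransferase gene Mfng at least 11.8-fold lower (adjusted p = 0.00581). In the list of VEGF and angiopoietin signalling 2 of 19 members were higher and 3 lower, with 3 and 5 when adjusted over the list alone (camera, adjusted p = 0.270). Flt1, the VEGF receptor 1 gene, was at least 87.3-fold lower in LEC (adjusted p = 4.10e-05) and Ptprb, the phosphatase of TIE2, 4.30-fold lower (adjusted p = 6.92e-04), whereas Flt4 and Nrp2 were higher.

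In the BMP and TGF-beta list 2 of 26 members were higher and 3 lower, with 5 and 7 when adjusted over the list alone, and its mean logFC (0.12), its median (-0.07) and its test (camera, below 0, adjusted p = 0.791) differed in sign. The mean was -0.15 with equal array medians and -0.26 with equal hybridisation controls. Besides Tgfb3 on the LEC side, the activin subunit gene Inhbb was at least 20.2-fold lower in LEC (adjusted p = 2.24e-04), the inhibitory SMAD gene Smad7 at least 8.50-fold lower (adjusted p = 0.00833) and the BMP target Id3 4.74-fold lower (adjusted p = 0.0174, and 0.0501 to 0.0856 without BEC replicate 2 or 4 or LEC replicate 2). Of 36 endothelial transcription factors, 5 were higher and 6 lower, with 6 and 10 when adjusted over the list alone (camera, adjusted p = 0.259). Prox1 led the higher ones. Mecom (at least 17.1-fold, adjusted p = 0.00628, and at least 27.6-fold without LEC replicate 3), the arterial factor Sox17 (at least 55.8-fold, adjusted p = 1.32e-04) and Tcf15, 15.5-fold lower (adjusted p = 8.62e-04), led the lower ones.

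Genes of leukocyte traffic were divided. Ackr2, a scavenging receptor of inflammatory chemokines, was at least 72.4-fold higher in LEC (adjusted p = 0.00222), and at least 164-fold without BEC replicate 1. Lower in LEC were the junctional adhesion molecules Jam2 (at least 46.8-fold, adjusted p = 5.83e-05) and Jam3 (at least 12.1-fold, adjusted p = 0.0164) and the gut addressin gene Madcam1 (at least 4.97-fold, adjusted p = 0.00158). Jam3 missed the threshold (adjusted p = 0.0522 to 0.0592) without BEC replicate 1, 2 or 4. Of 33 members 5 were higher and 8 lower, with 5 and 12 when adjusted over the list alone, and the list missed the threshold (camera, adjusted p = 0.0526, but 0.0220 to 0.0371 without LEC replicate 1, 2 or 4). It was called lower under 9 of 25 alternatives (adjusted p up to 0.261 over all). Of 25 junction genes 2 were higher and 6 lower, with 5 and 7 when adjusted over the list alone (camera, adjusted p = 0.259). Besides Jam2 and Jam3, the connexin 40 gene Gja5 was at least 11.5-fold lower (adjusted p = 0.0135, and 0.0562 without BEC replicate 1 or 2), and the polarity gene Pard6g was at least 117-fold higher in LEC (adjusted p = 1.22e-04).

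Basement membrane genes were lower in LEC as a list, with 2 of 25 members higher and 8 lower, and 2 and 10 when adjusted over the list alone (camera, adjusted p = 1.98e-04, and adjusted p = 0.176 with an estimated correlation). The laminin gene Lama3 was at least 26.7-fold lower (adjusted p = 5.39e-04), and the collagens Col4a3 at least 6.42-fold (adjusted p = 0.0158) and Col15a1 26.8-fold lower (logFC -4.74 ± 0.72, adjusted p = 0.00154), whereas Col18a1 was 26.9-fold higher (logFC 4.75 ± 0.59, adjusted p = 3.00e-04). Without BEC replicate 4 the difference was at least 10.01-fold for Col4a3 and 40.2-fold for Col15a1. The adjusted p of Col4a3 was 0.0590 to 0.0658 without BEC replicate 1, 2 or 3. The other kept probe set of Lama3, of Col4a3 and of Jam3 had the same sign and was not called.

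Genes of fatty acid and lipoprotein handling were lower in LEC as a list, with 1 of 27 members higher and 3 lower, and 2 and 8 when adjusted over the list alone (camera, adjusted p = 1.49e-04, and adjusted p = 0.0917 with an estimated correlation). The fatty acid transporter Cd36 was at least 41.7-fold lower (adjusted p = 7.79e-04), the HDL receptor gene Scarb1 at least 32.8-fold lower (adjusted p = 9.73e-05) and the fatty acid binding protein gene Fabp4 15.2-fold lower (adjusted p = 5.74e-04). Fabp4 remained bright in LEC, at 9.31 ± 1.27 (SD, n = 4). Without LEC replicate 1 the difference was at least 23.1-fold for Cd36 and 9.89-fold for Fabp4, and without LEC replicate 4 at least 70.5-fold for Cd36. The VLDL receptor gene Vldlr was at least 35.1-fold higher in LEC (adjusted p = 0.00127), but none of its 4 other kept probe sets was called (logFC 1.54 to 3.82). Its adjusted p was 0.132 with the probe sets prone to cross-hybridisation left out and between 1.65e-04 and 0.0143 under the other alternatives. In the hemostasis list, which besides coagulation and fibrinolysis holds vasoactive genes such as Nos3 and Edn1, 3 of 22 members were higher and 3 lower. When adjusted over the list alone these numbers were 7 and 6. Its mean and median logFC were below 0 (-0.58 and -0.14) and its test above 0 (camera, adjusted p = 0.982). Mmrn1 was joined by the protein S gene Pros1, 2.83-fold higher (adjusted p = 0.0437), and the endothelin-converting enzyme gene Ece1, 1.99-fold higher (adjusted p = 0.0126, from 0.00369 to 0.398 over all alternatives, the highest with equal hybridisation controls, and with no other kept probe set called). Without BEC replicate 1, 2 or 3 or LEC replicate 2, 3 or 4 the adjusted p of Pros1 was 0.0974 to 0.139, and it was 0.278 with equal array medians and up to 0.486, with equal hybridisation controls.

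Interferon-induced genes were lower in LEC as a list. Of 24 members 0 were higher and 6 lower, with 10 lower when adjusted over the list alone (camera, adjusted p = 1.72e-06, and adjusted p = 0.116 with an estimated correlation). Rsad2, the antiviral protein viperin, was 14.8-fold lower (11.87 ± 0.11 in BEC and 7.98 ± 1.23 in LEC, SD, n = 4, adjusted p = 6.56e-04), Oasl2 at least 8.71-fold lower (adjusted p = 0.0197) and the transcription factor gene Irf1 6.36-fold lower (adjusted p = 0.0108). Irf1 missed the threshold (adjusted p = 0.0560) without BEC replicate 2. That of Oasl2 was 0.0527 with the mouse as a replicate block and 0.0548 to 0.0728 without BEC replicate 1, BEC replicate 3 or LEC replicate 4. Among antigen presentation genes 0 of 16 were higher and 1 lower, with 0 and 3 when adjusted over the list alone (camera, adjusted p = 0.0140). The adjusted p was 0.229 with an estimated correlation, 0.0557 with no intensity trend and 0.0719 without LEC replicate 4. The called gene, the class I gene H2-K1, was 2.66-fold lower (adjusted p = 0.0491), a call that was lost when any array but LEC replicate 2 was left out (0.0517 to 0.139). None of its other kept probe sets was called (logFC -1.15 to -0.64).

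Of the 20 cell cycle genes limma called 0, over all genes or adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. Camera gave adjusted p = 0.982 with a test direction above 0, a median logFC of -0.04 and a mean of 0.20, which was -0.08 with equal array medians and -0.19 with equal hybridisation controls. The lowest p was that of the replication licensing gene Mcm3 (logFC -1.76 ± 0.61, adjusted p = 0.162). Of 27 immediate early and stress genes, 0 were higher and 1 lower, with 2 and 6 when adjusted over the list alone (camera, adjusted p = 0.184). The called gene was Zfp36, an mRNA decay factor, 5.06-fold lower in LEC (adjusted p = 0.00121).

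**Figure D3:**
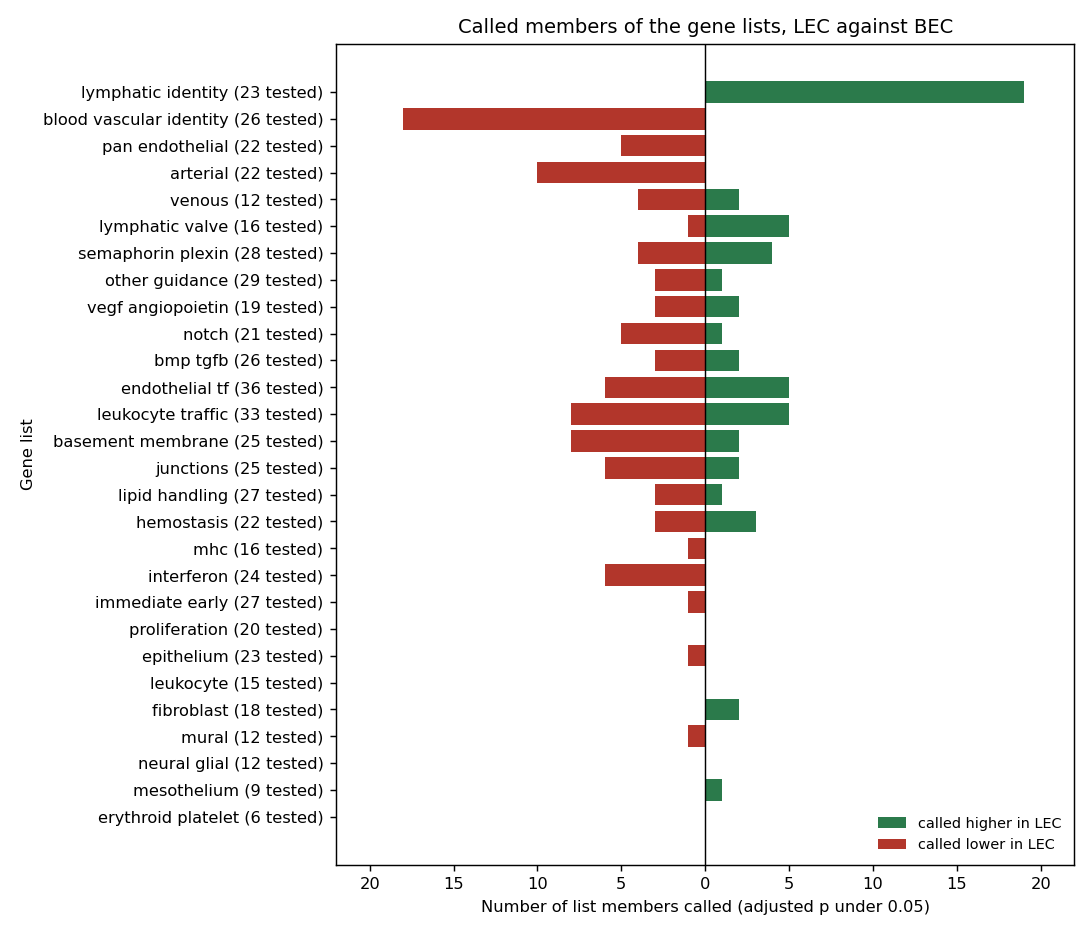
Number of members called higher in LEC (right of 0) and lower in LEC (left of 0) at an adjusted p under 0.05, for each of the 28 gene lists tested, with the number of members tested in brackets (vertical axis). The lymphatic identity list has 19 members higher and the blood vascular identity list 18 lower, while the semaphorin and plexin list has 4 in each direction.

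Markers of other cell types differed between single arrays. The mean of 23 epithelial genes was 9.50 in BEC replicate 3, 7.30 in BEC replicate 4 and 7.81 in LEC replicate 3, and between 4.23 and 5.43 on the other 5 arrays. As a list they were lower in LEC (camera, adjusted p = 0.00892), but the adjusted p was 0.498 with an estimated correlation and 0.408 without BEC replicate 3. Of their members 0 were higher and 1 lower, with 0 and 2 when adjusted over the list alone. The called gene was the carbonic anhydrase Car4 (at least 54.1-fold lower, adjusted p = 0.0120), which was bright on all 4 BEC arrays (11.79 to 13.34). Its bound was 105-fold without LEC replicate 1 and 29.6-fold without LEC replicate 2. The adjusted p of Car4 ran from 1.73e-04 to 0.0684 over the alternatives, the highest without mouse 4. The mean of 18 fibroblast genes was 4.40 to 4.95 in BEC and 5.52, 8.41, 5.70 and 7.25 in LEC replicates 1 to 4. Of these, 2 were higher and 0 lower, with 7 and 1 when adjusted over the list alone (camera, adjusted p = 8.58e-05, and adjusted p = 0.234 with an estimated correlation). The called genes were Thy1 and the fibulin gene Fbln1, 15.8-fold higher (adjusted p = 0.0194), a difference of 26.7-fold without LEC replicate 1 and 9.19-fold without LEC replicate 2. The adjusted p of Fbln1 was 0.0549 to 0.0609 without BEC replicate 2, 3 or 4 or LEC replicate 2 or 4, and neither of its other kept probe sets was called (logFC 1.15 to 2.68).

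Of 9 mesothelial genes 1 was higher and 0 lower, also when adjusted over the list alone (camera, adjusted p = 0.0106). The adjusted p was 0.176 with an estimated correlation, 0.0571 without LEC replicate 3 and 0.234 with the stricter filter. The called gene was the membrane glycoprotein gene Gpm6a, at least 101-fold higher and even over the LEC arrays (11.69 ± 0.16, SD, n = 4, adjusted p = 8.56e-05). Of 12 mural genes 0 were higher and 1 lower, also when adjusted over the list alone (camera, adjusted p = 0.693), with Rgs5, known from pericytes, at least 27.9-fold lower in LEC (adjusted p = 0.00849). Of the 15 leukocyte, 12 neural and glial and 6 red cell and platelet genes limma called 0, also when adjusted over the list alone. At an unadjusted p under 0.05, 2, 2 and 0 of them were higher and 0 lower. Camera gave adjusted p = 0.157, 0.982 and 0.455. The mean of the leukocyte list was higher in LEC in 4 of 4 mice, and camera called it under 4 of 24 alternatives (adjusted p from 0.0151 to 0.408 over all), among them without LEC replicate 3 (0.0424). Their lowest p-values were those of the macrophage gene Adgre1 (logFC 3.30 ± 1.15, adjusted p = 0.167), the tubulin gene Tubb3 (logFC 2.90 ± 1.14, adjusted p = 0.238) and the integrin gene Itgb3 (logFC 1.15 ± 0.54, adjusted p = 0.351, and 0.0297 without LEC replicate 1). The mean and median logFC of the neural and glial list were below 0 (-0.10 and -0.25) and its test above 0.

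**Figure D4:**
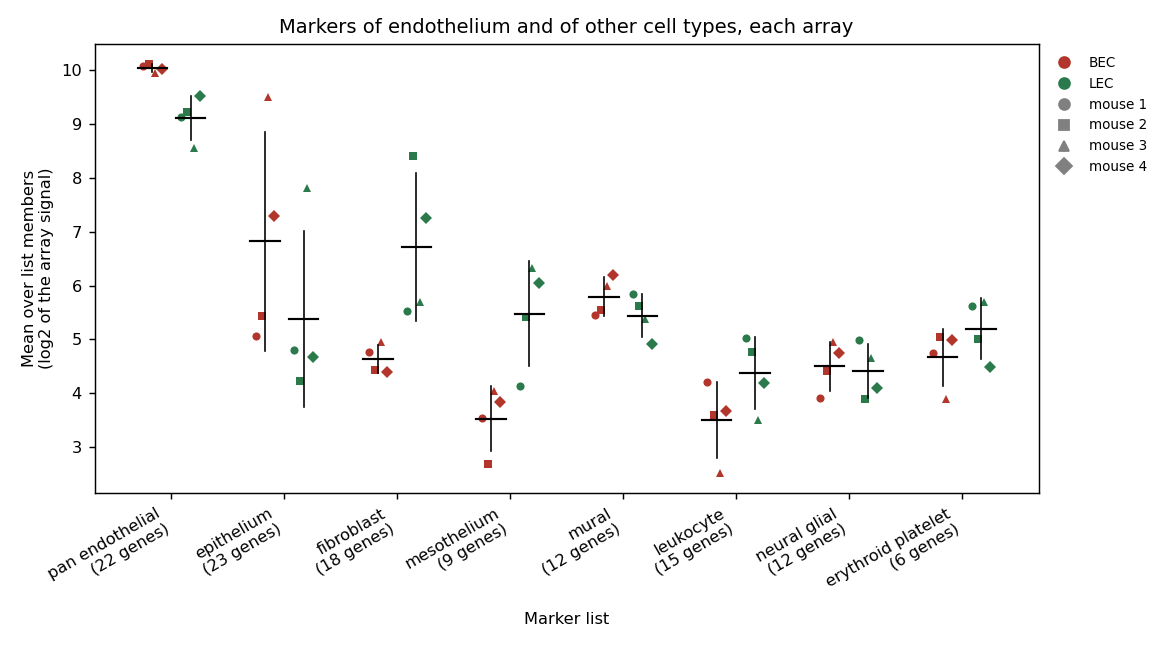
Mean log2 signal over the members of each marker list (vertical axis) on each of 4 BEC and 4 LEC arrays, for endothelium and 7 other cell types (horizontal axis); symbols mark the mouse, bars the mean and lines 1 SD. Epithelial markers are high in both arrays of mouse 3 and in BEC of mouse 4, and fibroblast markers in LEC of mice 2 and 4.

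Of the 8 measures of array quality, none passed an unpaired test between the cell types, but several had the same sign in all 4 mice. The log2 ratio of the 3' to the 5' control probe set of Gapdh was 3.00 ± 0.42 in BEC and 2.61 ± 1.12 in LEC (SD, n = 4, exact permutation p = 0.629), and that of actin -0.19 ± 0.36 and -0.29 ± 0.15 (exact permutation p = 0.657). Array medians were 4.09 ± 0.26 in BEC and 4.37 ± 0.30 in LEC, higher in LEC in 4 of 4 mice (exact permutation p = 0.200). The hybridisation controls were 12.95 ± 0.48 and 13.34 ± 0.49, also higher in LEC in 4 of 4 mice (exact permutation p = 0.343). Background levels (3.70 ± 0.54 and 4.26 ± 0.46, exact permutation p = 0.200) and 18S controls (13.87 ± 0.38 and 14.20 ± 0.41, exact permutation p = 0.286) were higher in LEC in 4 of 4 mice as well. The median Spearman correlation within the group was lower in LEC in 4 of 4 mice (0.745 ± 0.032 and 0.687 ± 0.058, exact permutation p = 0.114). The adjusted p was at least 0.457 for each measure. Within mice, LEC minus BEC was 0.33 ± 0.04 for the 18S controls and 0.39 ± 0.09 for the hybridisation controls (mean ± SD of 4 pairs), larger than the spread between pairs. For both the exact sign-flip p was 0.125, the smallest that 4 pairs allow.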

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

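The test of background in mouse 3 and the test of Thy1 were chosen only after the result was seen. For 115 values (named genes, list means and array measures), the highest or lowest of the 4 arrays of a group was compared with the others. The gap to its nearest neighbour, as a share of the group's whole range, passed the 95% critical value of Dixon's test in 16 of 230 groups, and chance gives about 1 in 20, or 11.5. The sexes were compared too, and for 0 of these values did all 3 females differ between LEC and BEC in 1 direction and the male in the other. That result was largely set in advance, since 74 of the values are called genes and 539 of the 540 called genes had the same sign in all 4 mice. With 1 male it says nothing about sex.

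Among array measures, BEC replicate 1 stood apart in its hybridisation controls (13.67 against 12.64 to 12.75, share 0.898), its background level (4.52 against 3.43 to 3.43, share 0.994) and its median Spearman correlation within the group (0.696 against 0.760 to 0.763, share 0.952). LEC replicate 1 stood apart in the last measure (0.601 against 0.711 to 0.724, share 0.899). It was also the highest LEC array in hybridisation controls (14.05 against 12.91 to 13.24) and background level (4.88 against 3.83 to 4.32), without passing the critical value. Both arrays of mouse 1 had the lowest array quality weights, 0.774 in BEC and 0.464 in LEC. Among BEC arrays, Ackr2 was 8.15 in replicate 1 and 2.68 to 2.96 in the others (share 0.949), and its bound of 72.4-fold was 164-fold without that array. Col4a3 was 5.02 in BEC replicate 4 and 7.46 to 7.71 in the others (share 0.908). Madcam1 was 7.71 in BEC replicate 3 and 6.02 to 6.31 in the others (share 0.8292), and Plscr2 was 9.07 there and 9.89 to 10.05 in the others (share 0.834).

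Among LEC arrays, replicate 1 was highest in Lyve1 (14.23 against 13.44 to 13.53, share 0.882), Sema3d (11.74 against 9.68 to 9.95, share 0.870) and Tcf15 (6.57 against 5.33 to 5.51, share 0.850). LEC replicate 3 was lowest in Epha4 (3.93 against 4.71 to 4.86, share 0.837) and highest in Hey2 (6.26 against 3.14 to 3.48, share 0.891). Rgs5 was -0.97 in LEC replicate 4 and 4.71 to 5.55 in the others (share 0.871). The mean of the basement membrane list was 7.74 in LEC replicate 3 and 8.18 to 8.22 in the others (share 0.915). The mean of the epithelial list was 7.81 in LEC replicate 3 and 4.23 to 4.81 in the others (share 0.839).

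Epithelial genes were high in both cell types of mouse 3, and also in BEC of mouse 4 (Epcam 11.13, Krt19 10.10), which counts among the other mice below. Of 35 further epithelial genes listed before their values were seen, 29 were higher in mouse 3 than in the mean of the other mice in both cell types, with a median excess of 2.87 ± 0.40 (SE) log2 units in BEC and 3.25 ± 0.53 in LEC. Of the 36 listed, 0 stood on another list and 6 lay above background on all 8 arrays, and abundant ones were Lypd8, at 13.08 in BEC and 11.66 in LEC of mouse 3, and Pigr, at 12.12 and 11.51, against 9.35 and 11.32 in BEC of mouse 4. A raised background or scaling of the arrays was argued against by 65 markers of 4 other cell types, whose larger median excess was 0.0193 ± 0.378 (SE), below the bound of 0.955 derived from the epithelial excess. Epithelial RNA in both sorted samples of mouse 3 is a candidate source, although a gate on CD31, if used, would remove epithelial cells, and the way it could have entered and a difference in this mouse's biology stay open, untested.

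Genes of the fibroblast list, of which 0 of 20 stood on another list and 5 lay above background on all 8 arrays, were on average higher in LEC and uneven over its arrays, with 2 of 18 members called, Serpinf1 and Pi16 lower without a call, and adjusted p = 0.234 with an estimated correlation. Col1a2 was 6.20, 10.84, 6.85 and 11.20 and Col3a1 7.69, 11.64, 6.80 and 9.83 in LEC replicates 1 to 4. Over these arrays 30 further fibroblast genes followed the list's mean with a median r of 0.620 ± 0.118 (SE, across genes, which are not independent), against -0.0137 over all genes. Their median LEC minus BEC difference was 1.06 log2 units, but they did not all go one way. Col8a1 was called lower in LEC (7.48 to 8.43 in BEC, -0.22 to 6.66 in LEC), and Igf1, Lox and Adamts5 were also brighter in BEC on average. Fibroblast RNA in some LEC samples is a candidate source of the fibroblast genes brighter in LEC, although a gate on CD31, if used, would remove fibroblasts, which can carry podoplanin. As a set, 231 genes called higher in LEC followed the list only weakly, with a median r of 0.190 ± 0.0445. The call itself favours genes that are even over the LEC arrays. A low r was thus likely from the start and is weak evidence against fibroblast RNA as their source. Of these genes 6.93% (16 genes) had an r over 0.9, against 3.72% of all genes, so that source stays open for part of them. Thy1 ranged over 0.379 log2 units where the mean of the rest of the list ranged over 3.06 (ratio 0.124). As a called gene Thy1 was also likely to be even over the LEC arrays. Its small range is thus weak evidence against fibroblasts as its main source. Expression of fibroblast genes by LEC themselves stays open, untested.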

How the results depend on the processing

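Adding 16 to the linear signal and scaling to the hybridisation controls were chosen after seeing the data. For lists past no threshold, the direction is the sign of the mean logFC. Over 25 alternatives, 1803 of 1973 values of named genes kept direction and side of the threshold, 169 no longer passed it, 1 now passed it and 0 reversed, and 49 of 74 called named genes were called under all that tested them. Without the intensity trend 11 named genes lost their call: Car4, Cldn11, Efnb1, Fbln1, Id3, Irf1 and Mcam (adjusted p 0.0506 to 0.0649), and Ece1, H2-K1, Nrp2 and Pros1 (0.237 to 0.385). The antigen presentation list also lost its call (0.0557). Calls were lost with the floor for Slit3 (0.0525), with array weights for H2-K1, with quantile normalization for Nrp2 and without cross-hybridising probe sets for Vldlr. No filter ended those of Efnb1, Epha4, H2-K1 and Pros1, the mean of probe sets those of Ece1, Fbln1 and H2-K1, and the stricter filter those of the venous (0.0919) and mesothelial (0.234) lists. Calls were lost with equal array medians for Ece1, Nrp2, Pros1 and Sema4d, and with equal hybridisation controls for these and Efnb1, Fbln1 and Nr2f2. Mecom, Mfng, Selp and Smad7 lost theirs only without 1 or more of the mice, with an adjusted p of up to 0.0817, 0.0634, 0.0702 and 0.109. The fixed mouse block changed no call of a named gene or list but those of Oasl2, Epha4, Efnb1 and the venous list. It called 534 genes, 474 of them among the 540, and the random mouse block called 697, which held all 540. A total of 11 lists lost their call with an estimated correlation. By fry the antigen presentation (adjusted p = 0.110) and epithelial (0.404) lists lost theirs, and the junction (0.00299), leukocyte traffic (0.0214) and VEGF and angiopoietin (0.0435) lists passed. The last of these also passed with the mean of probe sets (0.0277). Of 754 values of lists, 676 kept both, 26 no longer passed the threshold, 17 newly passed it and 35 reversed.

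With every probe set tested, which counts some genes more than once and includes probe sets that name no gene, 424 probe sets were higher in LEC (234 genes in the main test) and 530 probe sets lower (306 genes). There were 420 genes at least 2-fold higher in LEC and 530 genes at least 2-fold lower in LEC. Scaling to hybridisation controls gave 123 higher, 123 of them by 2-fold or more. Leaving out arrays or mice, which leaves fewer samples, gave 107 to 227 higher and 149 to 329 lower, and 107 to 223 and 149 to 329 by 2-fold or more. The lowest were without mouse 2 (107 and 149) and mouse 4 (116 and 152).

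Lists past no threshold reversed in mean logFC. The other guidance list was -0.0498 with quantile normalization, -0.175 with equal medians, -0.568 with the stricter filter, -0.0720 with the mean of probe sets and -0.287 with hybridisation controls. BMP and TGF-beta genes gave -0.152 with equal medians, -0.0399 with the floor, -0.184 with the stricter filter, -0.0264 with 16 added and -0.264 with hybridisation controls. Cell cycle genes gave -0.0760, -0.136 and -0.188 with equal medians, the stricter filter and hybridisation controls. Transcription factors gave 0.0109 with the floor, 0.0998 with the mean of probe sets and 0.0512 without cross-hybridising probe sets. Neural and glial genes gave 0.242 with the floor, 0.566 with the stricter filter, 0.0588 without cross-hybridising probe sets and 0.0838 with 16 added. Leaving out arrays or mice gave -0.0823 to 0.303 for other guidance, -0.0979 to 0.0516 for transcription factors and -0.490 to 0.0825 for neural and glial genes. Equal medians and equal hybridisation controls lower the logFC of every gene by the same amount. That amount is the LEC minus BEC difference in array medians (0.276) or in the controls (0.388). Reversals under these scalings follow from that shift. The cause of the other reversals was not tested. The 2 planned pseudocount alternatives, written for a linear table, were not run because the deposited table is log2. Adding 16 to the back-transformed signal was run. Signal near background limits the folds, which are bounds for 145 of the higher and 179 of the lower genes.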

Other observations

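All gene families below were chosen after their values were seen. Some genes not named so far were called. Igfbp5, a binding protein of insulin-like growth factors, was at least 148-fold higher in LEC (adjusted p = 1.38e-05) and Igfbp6 at least 6.02-fold higher (adjusted p = 0.0317), a call that was lost when any array but BEC replicate 3 and LEC replicate 1 was left out (adjusted p up to 0.0996). Igfbp7 was 5.04-fold lower (adjusted p = 3.14e-04) and remained at 11.14 in LEC. Of 29 collagen genes 4 were higher and 5 lower. Col23a1 was at least 14.5-fold higher (adjusted p = 0.00395) and Col4a5 at least 6.89-fold higher (adjusted p = 0.00870), while Col13a1 was at least 33.6-fold lower (adjusted p = 1.81e-04) and Col4a2 3.45-fold lower (adjusted p = 0.00158). The protease inhibitor genes Serping1, the inhibitor of complement C1, and Serpina3n were 17.8-fold and at least 14.3-fold higher in LEC (adjusted p = 1.77e-04 and 0.00117).

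Of 16 adhesion G protein-coupled receptors, Adgrg3 was higher in LEC and 4 were lower: Adgrg1 (at least 30.7-fold, adjusted p = 2.73e-04), Adgrl2 (at least 23.9-fold, adjusted p = 0.00347), Adgrl4 (9.09-fold, adjusted p = 0.00223) and Adgrf5 (2.36-fold, adjusted p = 0.0228). Of 41 potassium channel genes, Kcnk5 (at least 16.7-fold, adjusted p = 0.0116) and Kcnn3 (at least 26.8-fold, adjusted p = 0.00839) were higher in LEC, and Kcna5 (at least 34.9-fold, adjusted p = 1.36e-04) and Kcnn4 (at least 7.17-fold, adjusted p = 0.0288) lower. Of 18 WNT and Frizzled genes, Wnt5a (at least 3.88-fold, adjusted p = 0.0163) and Wnt9a (at least 11.6-fold, adjusted p = 0.0167) were higher and 0 lower. Of 20 integrin genes, Itga9 and Itgav (6.10-fold, adjusted p = 0.0117) were higher and Itga1 (6.69-fold, adjusted p = 0.0288) and Itga6 (4.88-fold, adjusted p = 0.00296) lower. Leaving out 1 array ended the calls of Adgrf5 (BEC replicate 1, 2 or 4 or LEC replicate 3 or 4, adjusted p up to 0.0861) and Kcnn4 (BEC replicate 1, 3 or 4 or LEC replicate 1 or 2, up to 0.102). It also ended those of Wnt5a (LEC replicate 3 or 4, up to 0.0640), Wnt9a (BEC replicate 2 or LEC replicate 2 or 4, up to 0.0618) and Itga1 (BEC replicate 1, 2 or 4 or LEC replicate 3, up to 0.0939). The difference was at least 14.5-fold for Adgrl2 without BEC replicate 2, at least 42.7-fold and 17.9-fold for Kcnn3 without BEC and LEC replicate 1, and 4.23-fold for Itga1 without LEC replicate 4. None of 22 such families was shifted in 1 direction against other genes by camera, the lowest adjusted p being 0.129. Families that go both ways can fail that test.

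Chgb was lower in LEC and uneven over the BEC arrays, at 5.43, 10.54, 12.88 and 13.67 in replicates 1 to 4. Enteroendocrine RNA in BEC samples is a candidate source, although a gate on CD31, if used, would remove these epithelial cells. Of the 30 enteroendocrine genes listed, 0 stood on another list and 4 lay above background on all 8 arrays. Tph1 (2.66, 6.15, 8.92 and 10.21) and Slc18a1 (1.46, 4.56, 7.18 and 8.48) had their highest BEC values on the same arrays. So did Chga, a member of the epithelial list, at 4.84, 7.14, 11.21 and 12.34 in BEC and 2.68 to 5.78 in LEC. Pax6 (5.86, 4.62, 3.50 and 3.28) and Sst (5.53, 6.89, 3.54 and 2.67) were lowest on those arrays. As a set, 25 further enteroendocrine genes followed Chgb with a median r of 0.404 ± 0.159 (SE, across genes, which are not independent). Their median difference was -0.18 ± 0.43. The mean of the epithelial list was 5.06, 5.43, 9.50 and 7.30 in BEC replicates 1 to 4, so it was also highest on replicates 3 and 4. It was 7.81 in LEC replicate 3, where Chgb was 0.80. The 4 arrays are too few to decide, so enteroendocrine RNA and expression by BEC cannot be told apart.

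Over the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as large a count of genes or lists. That share is under 0.05 only if the pairing within mice is set aside. Every other split also mixes LEC with BEC, which widens the spread within its groups, so chance is not excluded by this comparison. The real split called 540 genes and the highest other split 2. At 2-fold or more these numbers were 536 and 2. With the preset correlation the margin was small, 14 lists against 12 in the highest other split, which set BEC replicates 1, 2 and 4 with LEC replicate 1 against the rest. With an estimated correlation 3 lists passed against 0. Of the 8 splits that part all 4 pairs, the highest other called 0 genes and 9 lists with the preset correlation, and 8 splits are too few for a share under 0.05. A list past the threshold with that correlation alone is therefore weaker evidence than one past both.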
